A study of Homo sapiens with 20 samples.

How the data were processed

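Total RNA from A549 cells exposed to 0, 100, 200 or 400 µg/ml crystalline silica for 6 hours had been labelled with biotin as cRNA and measured on 20 Illumina BeadChip arrays, 5 per dose. The deposited unnormalized table gives an intensity per sequence and array, as mean bead signal without normalization. Per the file headers the same table gives a detection p-value of each intensity against the negative control beads of its array. Per the file headers it also gives bead numbers (another kind of value, the mean number of beads behind each intensity), with a median of 19. It holds 37846 sequences, 1 per gene name, and 18.4% of them have bead numbers that are not whole, which were read as averages over several probes of a gene; the file does not state this. The authors' own table holds 15652 sequences as normalized log2 values, which track log2 intensity at high levels and are compressed at low levels; 15653 sequences were detected on at least 1 array. Per the labels BeadStudio, lumi and limma were used, with no versions or roles given. All columns belonged to the 20 listed samples (0 columns of other samples).

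Intensities were processed with neqc in limma 3.58.1 under R 4.3.3: normexp background correction from the detection p-values, an offset of 16, quantile normalization between arrays and log2. Sequences with detection p under 0.01 on at least 5 arrays were kept (9955), and a gene was represented by its sequence with the highest mean, which left 9910 genes. Of these 9092 had a reference name. Names came from a RefSeq gene table of assembly GRCh38.p14, used for names only: 20467 sequences matched by Entrez identifier, 53 by accession and 17326 kept the name in the file, and 632 shared a current symbol with another. The median log2 intensity over all sequences was 6.59.

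Groups and replicates were taken from the labels. limma fitted 1 mean per dose to all 20 arrays (16 residual degrees of freedom) with empirical Bayes moderation, and every pair of doses was contrasted. A second model took dose as a number in units of 100 µg/ml. Adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The median SE of a log2 change was 0.0434. A total of 34 gene lists with 905 entries was written from general knowledge, and those with at least 5 measured members (32) were tested with camera, which sets a list against all other genes, at a preset correlation of 0.01, with adjustment over the lists. The macrophage and leukocyte list and the endothelial list had fewer measured members and were not tested. The tested lists shared 10 genes: SOD2, IER3, CCN1, NQO1, SLC7A11, SESN1, BAX, BIRC5, BNIP3 and ID2. The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, apart from those said to be chosen later.

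The rule for named genes took, among genes past the threshold whose 5 treated arrays all lay above or all below the 5 arrays of the other group, the largest 12 rises and 10 falls at 400 µg/ml, 8 and 6 at 200 µg/ml, 6 and 4 at 100 µg/ml, and 4 and 4 for 200 against 100 and 400 against 200 µg/ml, or fewer where fewer passed. It also took the 3 members of each tested list with the smallest p at 400 µg/ml, whether or not they passed. Names covering several genes or none were left out. This gave 116 genes, of which some are not reported here.

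Alternatives replaced 1 choice at a time: the authors' values, no background correction, median scaling, cyclic loess, an offset of 50, no filter on detection, detection on all 20 arrays, only the 2 groups compared, eBayes with trend and robust options, array weights, the replicate number as a block, the number at the end of the description as a random block (duplicateCorrelation with statmod 1.5.0), the mean over a gene's sequences, a minimum fold of 1.5, dose as rank or without controls for the trend, camera with an estimated correlation, fry, and each array left out in turn. Chosen after seeing the data were a block for the 4 bright arrays (median intensity above 2 times that of the middle array), a block for the 5 order sets (every 4 arrays in the order of the samples, with 1 array per dose in each), a fit without the bright arrays and a fit without the 3 arrays with the lowest mean correlation with their groups. A block by slide was not run, since no file names the slide of an array. Counts over 100 splits of the arrays (the real one included), 200 simulated data sets of unchanged groups and 10000 random gene lists served as references. Array measures were compared by exact two-sided permutation tests. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

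The procedure was tested on simulated data with 9317 genes. For 400 against 0 µg/ml it called 57% of 100 genes changed 1.5-fold and 88% of 100 genes changed 2-fold, with mean estimates of 0.58 and 0.94 on the log2 scale, and 7 of 9117 unchanged genes. The changed genes were drawn only from those with a control level above 8, so these shares do not cover weaker genes. Errors were drawn independently for each gene and array, without the deviations that sets of real arrays share. It found 2 of 2 lists in which every member had been raised by 0.5 in log2 intensity at 400 µg/ml. It called 0 others, with 31 lists tested in all. Lists with smaller shifts, or with members that move both ways, are not covered by this.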

Results

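Gene expression was measured on 20 Illumina BeadChip arrays in A549 cells, an established human lung epithelial line. The cells had been kept for 6 hours in medium without serum, with crystalline silica, the mineral dust whose inhalation causes silicosis, at 0, 100, 200 or 400 µg/ml. Each dose had 5 arrays. The labels number the replicates and do not say that they were separate cultures, so the p-values measure the spread between samples, which may be technical. All 5 control titles and no treated title carry a letter after the replicate number. The numbers in the descriptions run from 1 to 6 at 100 and 400 µg/ml and from 7 to 12 at 0 and 200 µg/ml. No label says what the letter or these numbers mean, and a difference in handling behind the letter could not be separated from the presence of silica. A difference behind the ranges of numbers could not be separated from dose, except for 200 against 0 and 400 against 100 µg/ml, where both groups share a range. The number of arrays limits the precision of every value. On each array 8041 to 9647 of the 37846 measured sequences were detected, with group means of 9106 ± 362, 8897 ± 450, 8771 ± 518 and 8780 ± 461 (SD, n = 5) at 0, 100, 200 and 400 µg/ml. Signal over background, the 95th percentile of intensity over its median, was 6.4 to 8.88. No difference of a treated group from the controls in detected sequences, median intensity or signal over background passed the test (exact two-sided permutation p from 0.246 to 0.865, n = 5 against 5, each 0.865 after adjustment over the 9 tests). In every group 1 array was brighter: the 4 bright arrays had median intensities of 191 to 200 and the other 16 of 68.2 to 75.4. After normalization the deviations of the bright arrays from their groups correlated across genes at 0.224 to 0.292 (6 pairs). Those of 3 other arrays (control replicate 1, 200 µg/ml replicate 1 and 400 µg/ml replicate 2) correlated at 0.284 to 0.380. In the order of the samples every 4 arrays in turn form a set with 1 array per dose. The 4 bright arrays are the first of these 5 order sets, and the 3 others lie in the fourth. Deviations of arrays of the same set correlated at 0.123 on average (30 pairs), and those of other pairs from different groups at -0.0301 (120 pairs). Genes are not independent replicates in such a correlation. Changes below are log2 differences of group means ± SE from limma (n = 5 arrays per group), and levels are log2 intensities as mean ± SD.

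**Figure D1:**
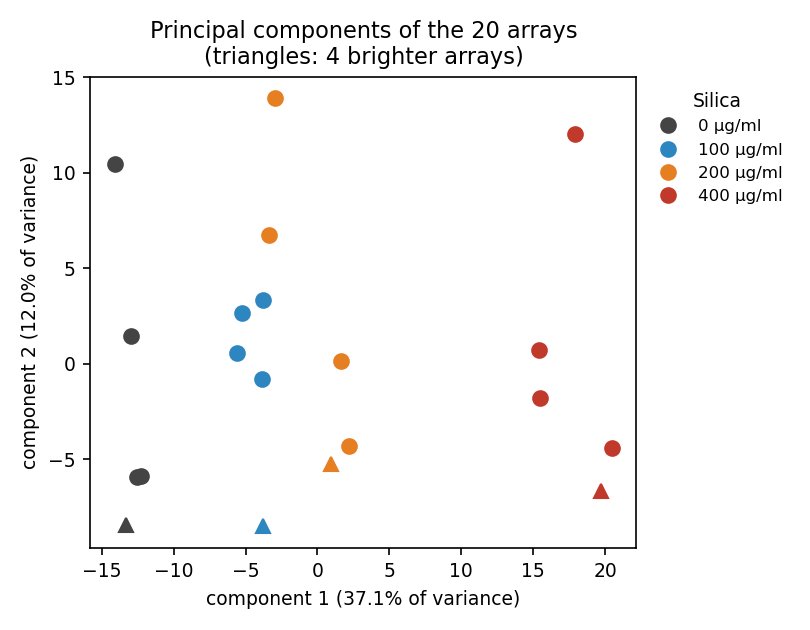
Position of the 20 arrays on the first and second principal components of the log2 intensities (unitless scores, with 37.1% and 12% of the variance), coloured by silica dose, with triangles for the 4 brighter arrays. The 5 arrays at 400 µg/ml lie at the right, the controls at the left and the 100 and 200 µg/ml arrays between them.

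The comparison of 100 µg/ml with the controls asks what the lowest dose changed in these cells. CXCL8, which encodes the neutrophil-attracting chemokine interleukin 8, rose most, by 2.92 ± 0.18 (7.54-fold, adjusted p = 1.94e-08), from a level of 8.12 ± 0.29 to 11.03 ± 0.08. FOSB, a subunit of the transcription factor AP-1, rose by 2.22 ± 0.13. PPP1R15A, which directs the dephosphorylation of eIF2α after stress, rose by 1.62 ± 0.09, and TMEM158, a membrane protein induced by RAS signalling, rose by 1.52 ± 0.10. ID2, an inhibitor of differentiation factors, fell by 0.75 ± 0.10, and the histone acetyltransferase gene KAT2A fell by 0.56 ± 0.11.

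Of the gene lists, 9 lay higher and 4 lower at 100 µg/ml than the other genes (camera, 32 lists tested). Among 19 measured immediate early genes, the transcription factors and signals induced first after a stimulus, 5 rose and 14 did not pass the test (10 rose when adjusted over the list alone; list adjusted p = 2.14e-16). They included CCN1, a secreted matrix protein, at 1.02 ± 0.07, and KLF6 at 1.15 ± 0.19. Of 16 genes of the MAP kinase feedback list 3 rose (5 when adjusted over the list alone; list adjusted p = 2.08e-06), led by the phosphatase gene DUSP5 at 1.14 ± 0.11 and PHLDA1 at 1.0 ± 0.11. Of 21 NF-κB feedback genes 2 rose (5 when adjusted over the list alone; list adjusted p = 2.08e-06): BIRC3, an inhibitor of apoptosis, by 0.78 ± 0.11 and the NF-κB inhibitor NFKBIA by 0.48 ± 0.09. Of 22 genes of the integrated stress response, which ATF4 drives, PPP1R15A and CEBPB rose (5 genes when adjusted over the list alone; list adjusted p = 5.84e-06), CEBPB by 0.33 ± 0.05. Of 21 YAP and SRF targets CCN1 and RND3 rose, RND3 by 0.87 ± 0.15 (4 genes when adjusted over the list alone; list adjusted p = 0.000125). CXCL8 alone rose among 16 NF-κB cytokine genes (2 when adjusted over the list alone; list adjusted p = 0.000312); for that list adjusted p = 0.123 with an estimated correlation.

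In the apoptosis list 2 of 23 genes rose at 100 µg/ml (3 when adjusted over the list alone; list adjusted p = 0.0289): TNFRSF21, a death receptor, by 0.56 ± 0.10 and BCL2L1, whose long form opposes apoptosis, by 0.53 ± 0.08. BCL2L1 was singled out after its values were seen. The lists of 26 ribosome biogenesis and 21 matrix remodelling genes lay higher with no member past the test (1 rose in each when adjusted over the list alone; list adjusted p = 0.0225 and 0.0215), and for matrix remodelling adjusted p = 0.0847 with an estimated correlation. The mitosis list lay lower with no fall among 31 genes (1 when adjusted over the list alone; list adjusted p = 0.00168). Of 6 fibroblast marker genes COL1A1, a fibrillar collagen, fell by 0.17 ± 0.03 (1 when adjusted over the list alone; list adjusted p = 0.000613). COL1A1 lay near the floor throughout, at 6.87 to 7.03 on the control arrays, where the lowest detected value of an array was 6.59 to 6.60. With silica it lay at 6.75 to 6.86, 6.72 to 6.79 and 6.64 to 6.74 at 100, 200 and 400 µg/ml. Of 14 TGF-β targets ID1 and ID2, both inhibitors of differentiation factors, fell (3 fell and 1 rose when adjusted over the list alone; list adjusted p = 0.0213); for that list adjusted p = 0.101 with an estimated correlation. None of 21 heat shock genes passed the test (1 fell when adjusted over the list alone; list adjusted p = 0.0215); for that list adjusted p = 0.0553 with an estimated correlation.

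In all, 88 of 9910 genes changed at 100 µg/ml: 55 rose and 33 fell, and 28 rose and 1 fell by at least 1.5-fold. The count was 102 with the order sets as a block, 93 with the bright arrays as a block and 45 on the 16 other arrays. It was 58 without a filter on detection and 20 with median scaling, and rises made up 62.5% of the changes, against 85.0% with median scaling, 78.0% without background correction and 76.1% from the authors' own values. Median scaling ended the calls of ID1, ID2, KAT2A, BIRC3, NFKBIA, CEBPB and RND3 at this dose, and the 16 other arrays those of NFKBIA and RND3. With only the 2 groups in the model KAT2A, COL1A1, ID1 and TNFRSF21 were not called, nor was KAT2A without the 3 arrays that deviated together. With the order sets as a block the apoptosis list (adjusted p = 0.0566) was not called.

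The rule for named genes also took KLF2, HOXA5 and SNORD13, which changed by 1.21 ± 0.28, -0.58 ± 0.12 and -0.50 ± 0.11 (adjusted p = 0.0459, 0.0332 and 0.0369). KLF2, an endothelial and immune transcription factor, lost the call with the order sets as a block and without any array but 100 µg/ml replicate 5 (adjusted p up to 0.123, and from 0.0155 to 0.224 over all alternatives). HOXA5, a developmental transcription factor, lost it without control replicates 1, 3 or 5 or 100 µg/ml replicates 1, 3 or 5 (adjusted p up to 0.102, and from 0.0105 to 0.536 over all alternatives). SNORD13, a small nucleolar RNA, lost it without control replicates 1, 2 or 5 or any 100 µg/ml array (adjusted p up to 0.111, and from 0.0222 to 0.480 over all alternatives). The list calls of apoptosis ended without control replicate 2 or 100 µg/ml replicates 3 or 4 (adjusted p up to 0.0698, and 0.00152 to 0.131 over all alternatives) and of heat shock without control replicates 2 or 5 or 100 µg/ml replicate 2 (up to 0.114, and 0.00231 to 0.114). Matrix remodelling ended without control replicates 3 or 5 or 100 µg/ml replicates 1 or 2 (up to 0.0632, and 0.00565 to 0.183). Ribosome biogenesis ended without control replicate 5 or 100 µg/ml replicate 4 (up to 0.0698, and 0.00342 to 0.0845), and TGF-β targets without 100 µg/ml replicate 2 (0.0642, and 0.00417 to 0.134).

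The comparison of 200 µg/ml with the controls asks what the middle dose changed. CXCL8 rose by 3.92 ± 0.18 (15.1-fold, adjusted p = 2.22e-10), FOSB by 2.51 ± 0.13 and PPP1R15A by 2.13 ± 0.09. TMEM158 rose by 1.96 ± 0.10, and STC1, which encodes the secreted hormone stanniocalcin, by 1.91 ± 0.12. DUSP5 rose by 1.68 ± 0.11, KLF6 by 1.65 ± 0.19 and JUN, an AP-1 subunit, by 1.52 ± 0.16. FZD2, a receptor for WNT ligands, fell by 1.07 ± 0.17, from a level of 9.63 ± 0.29 to 8.55 ± 0.23. ID2 fell by 0.95 ± 0.10, HOXA5 by 0.79 ± 0.12 and SMIM14, a small membrane protein, by 0.67 ± 0.12.

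At 200 µg/ml 9 lists lay higher and 3 lower than the other genes (camera). Of 19 immediate early genes 10 rose (14 when adjusted over the list alone; list adjusted p = 4.54e-20), among them EGR1 at 1.22 ± 0.20 and CCN1 at 1.33 ± 0.07. Of 21 NF-κB feedback genes 5 rose (10 when adjusted over the list alone; list adjusted p = 7.22e-12), BIRC3 by 1.37 ± 0.11 and NFKBIA by 0.63 ± 0.09. Of 16 NF-κB cytokine genes CXCL8 and PTGS2, the inducible cyclooxygenase, rose (6 when adjusted over the list alone; list adjusted p = 7.15e-08), PTGS2 by 1.25 ± 0.19. Of 22 stress response genes 6 rose (11 rose and 1 fell when adjusted over the list alone; list adjusted p = 1.06e-08), and TRIB3, an inhibitor of AKT, was at 1.28 ± 0.18. In the MAP kinase feedback list 3 of 16 rose (6 when adjusted over the list alone; list adjusted p = 6.82e-08): DUSP5, PHLDA1 by 1.31 ± 0.11 and DUSP1 by 0.58 ± 0.06. Of 21 YAP and SRF targets 4 rose (7 when adjusted over the list alone; list adjusted p = 2.80e-07), with RND3 at 1.25 ± 0.15. GNL3 and GAR1 rose among 26 ribosome biogenesis genes (4 when adjusted over the list alone; list adjusted p = 0.00266), GAR1 by 0.27 ± 0.06; GNL3 was chosen after its values were seen. Of 21 matrix remodelling genes 2 rose (5 when adjusted over the list alone; list adjusted p = 0.0134), among them the protease gene PLAU by 1.27 ± 0.28, which was chosen after its values were seen. For matrix remodelling adjusted p = 0.0593 with an estimated correlation. VEGFC alone rose among 8 genes of the growth factor list (ligands of the EGF receptor and related growth factors), by 0.31 ± 0.07 (2 when adjusted over the list alone; list adjusted p = 0.0168), where adjusted p = 0.0616 with an estimated correlation.

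Of 31 mitosis genes KIF20A, PTTG1 and HMMR, which act in spindle and chromosome movement, fell at 200 µg/ml (5 when adjusted over the list alone; list adjusted p = 0.000898), by 0.51 ± 0.12, 0.34 ± 0.08 and 0.50 ± 0.11. Single arrays ended these calls. KIF20A lost it without control replicate 1 or 200 µg/ml replicates 2, 3 or 4 (adjusted p up to 0.0596, and 0.00547 to 0.403 over all alternatives). PTTG1 lost it without control replicates 1 or 3 or 200 µg/ml replicates 1, 2 or 3 (up to 0.0691, and 0.0203 to 0.450), and HMMR without control replicate 3 (0.0514, and 0.00881 to 0.514). COL1A1 fell by 0.20 ± 0.03 among 6 fibroblast markers (2 when adjusted over the list alone; list adjusted p = 0.00204). The 36 oxidative phosphorylation genes lay lower with none past the test (0 when adjusted over the list alone; list adjusted p = 0.0330).

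In all, 307 of 9910 genes changed at 200 µg/ml: 190 rose and 117 fell, and 68 rose and 14 fell by at least 1.5-fold. The count was 371 with the order sets as a block, 341 with the bright arrays as a block and 186 on the 16 other arrays. It was 116 with median scaling, where rises made up 85.3% of the changes against 61.9%, and that scaling ended the calls of FZD2, HOXA5, SMIM14, GAR1 and VEGFC. GAR1 and VEGFC were also not called on the 16 other arrays, nor was PFDN5 with the order sets as a block. PFDN5 and CADM1, also named by the rule, fell by 0.88 ± 0.22 and 0.68 ± 0.15. PFDN5 lost the call without control replicates 1 to 4 or 200 µg/ml replicates 1 or 3 (adjusted p up to 0.103, and 0.0184 to 0.282 over all alternatives), and CADM1 without control replicate 5 or 200 µg/ml replicates 2 or 4 (up to 0.0552, and 0.00447 to 0.174). The list calls of growth factors and matrix remodelling ended without 200 µg/ml replicate 4 (0.0608, and 0.000538 to 0.0911) and 200 µg/ml replicate 3 (0.0626, and 0.00159 to 0.0626). Oxidative phosphorylation ended without control replicates 2 or 4 or 200 µg/ml replicates 4 or 5 (up to 0.0608, and 0.00343 to 0.0911).

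The comparison of 400 µg/ml with the controls asks what the highest dose changed. CXCL8 rose by 6.23 ± 0.18 (75.3-fold, adjusted p = 8.08e-14), from 8.12 ± 0.29 to 14.35 ± 0.09. EGR1, an immediate early transcription factor, rose by 4.75 ± 0.20 (26.8-fold), PTGS2 by 4.57 ± 0.19 (23.8-fold) and FOSB by 4.45 ± 0.13 (21.8-fold). On the control arrays EGR1 lay at 6.70 to 6.77, FOSB at 6.68 to 6.74 and PTGS2 at 6.80 to 6.93. The lowest detected value of an array was 6.59 to 6.60. Rises from so near that floor may be understated, here and at the lower doses, so their order against CXCL8 is uncertain. IL6, the cytokine interleukin 6, was detected on 0 of the 5 control arrays and was at least 8.14-fold higher. FZD2 fell most, by 1.87 ± 0.17, and the chaperone genes HSPA1A and HSPA2 fell by 1.67 ± 0.28 and 1.49 ± 0.19.

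Several lists of inflammatory and signalling genes, each tested by itself, lay higher at 400 µg/ml than the other genes (camera). Of 16 NF-κB cytokine genes 13 rose and 3 did not pass the test (13 when adjusted over the list alone; list median 1.12, adjusted p = 9.89e-21). Of the 13, IL6, CXCL1, CXCL2, CCL20, CSF2, IL1A and IL1B were detected on 0 of the 5 control arrays. The detection filter kept them only through treated arrays, and would have dropped cytokine genes that stayed silent. The share that rose may therefore be overstated, and the list's p too small. FGF2, DUSP16, MTHFD2 and MMP10, which rose in other lists, were also detected on 0 control arrays. Of 21 NF-κB feedback genes 20 rose (20 when adjusted over the list alone; list median 0.69, adjusted p = 1.75e-23): BIRC3 by 3.64 ± 0.11, NFKBIZ by 1.93 ± 0.10 and NFKBIA by 1.73 ± 0.09. IRAK2, a kinase downstream of interleukin 1 receptors, rose by 3.56 ± 0.27. Immediate early genes rose in 18 of 19 cases (18 when adjusted over the list alone; list median 1.27, adjusted p = 1.26e-28), with JUN at 3.43 ± 0.16, KLF6 at 3.5 ± 0.19 and ZFP36, which destabilises cytokine messenger RNA, at 3.82 ± 0.25. Of 16 MAP kinase feedback genes 9 rose (9 when adjusted over the list alone; list median 0.25, adjusted p = 1.76e-10): DUSP5 by 3.0 ± 0.11, PHLDA1 by 2.41 ± 0.11 and DUSP1 by 1.28 ± 0.06. Of 8 genes of the growth factor list 5 rose (5 when adjusted over the list alone; list median 0.11, adjusted p = 0.000222), the EGF receptor ligands HBEGF and EREG by 1.90 ± 0.13 and 0.32 ± 0.04, and VEGFC, which is not such a ligand, by 0.55 ± 0.07.

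Of 22 genes of the integrated stress response 13 rose at 400 µg/ml and SLC7A5, an amino acid transporter gene chosen after its values were seen, fell (the same numbers when adjusted over the list alone; list median 0.41, adjusted p = 1.66e-10). PPP1R15A rose by 3.92 ± 0.09, TRIB3 by 2.85 ± 0.18 and CEBPB by 1.52 ± 0.05. GDF15, a secreted stress cytokine, rose by 3.57 ± 0.27 and STC1 by 3.31 ± 0.12. Of 8 genes of the metallothionein list MT1A, MT2A and the regulator MTF1 rose (3 when adjusted over the list alone; list median 0.12, adjusted p = 0.0278), MT2A by 0.30 ± 0.08; for that list adjusted p = 0.0507 with an estimated correlation, and the call also ended with detection required on all 20 arrays. Of 26 ribosome biogenesis genes 10 rose (10 when adjusted over the list alone; list median 0.09, adjusted p = 0.000246), DDX21, a nucleolar helicase, by 0.90 ± 0.12 and NOLC1 by 0.57 ± 0.10. Of 19 genes with short-lived transcripts 11 rose and ID2 fell (11 rose and 2 fell when adjusted over the list alone; list median 0.10, adjusted p = 0.000246), with the splicing kinase CLK1 at 1.07 ± 0.09 and ZNF143 at 0.83 ± 0.06. Of 21 matrix remodelling genes 9 rose (10 when adjusted over the list alone; list median 0.14, adjusted p = 1.47e-05), with PLAUR, a receptor for the protease urokinase, at 1.06 ± 0.11. Of 21 YAP and SRF targets 8 rose (9 when adjusted over the list alone; list median 0.09, adjusted p = 0.000314), RND3 by 2.70 ± 0.15 and CCN1 by 1.8 ± 0.07.

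Of 31 mitosis genes at 400 µg/ml 12 fell and 19 did not pass the test (14 fell when adjusted over the list alone; list median -0.23, adjusted p = 1.47e-05): KIF20A by 1.36 ± 0.12, HMMR by 0.92 ± 0.11 and PTTG1 by 0.60 ± 0.08. Of 30 replication genes 11 fell and CCND1, the G1 cyclin D1, rose by 0.39 ± 0.06 (12 fell and 1 rose when adjusted over the list alone; list median -0.17, adjusted p = 0.00462), while the polymerase genes POLA2 and POLE2 fell by 0.74 ± 0.11 and 0.59 ± 0.10. For replication adjusted p = 0.126 with an estimated correlation. Of 36 oxidative phosphorylation genes 6 fell (1 when adjusted over the list alone; list median -0.15, adjusted p = 0.0123), UQCRFS1 of complex III by 0.21 ± 0.05, a call that median scaling ended. COL1A1, by 0.25 ± 0.03, and S100A4, by 0.21 ± 0.06, fell among 6 fibroblast markers (3 when adjusted over the list alone; list median -0.09, adjusted p = 0.0278); for that list adjusted p = 0.0569 with an estimated correlation. Its call ended without 400 µg/ml replicate 2 (0.0627, and 4.80e-06 to 0.0627 over all alternatives), and that of S100A4 without control replicates 1 or 5 (up to 0.0559, and 0.00374 to 0.0749). Of the fibroblast markers COL3A1, LUM and THY1 were detected on only 2, 3 and 3 of the 5 arrays at 400 µg/ml. Outside the lists MSRB1, which repairs oxidised methionine, fell by 1.39 ± 0.12, the splicing factor gene SRSF5 by 1.23 ± 0.12 and TNS3, of focal adhesions, by 1.14 ± 0.09. OXLD1 and HOXA5 fell by 1.17 ± 0.15 and 1.16 ± 0.12.

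**Figure D2:**
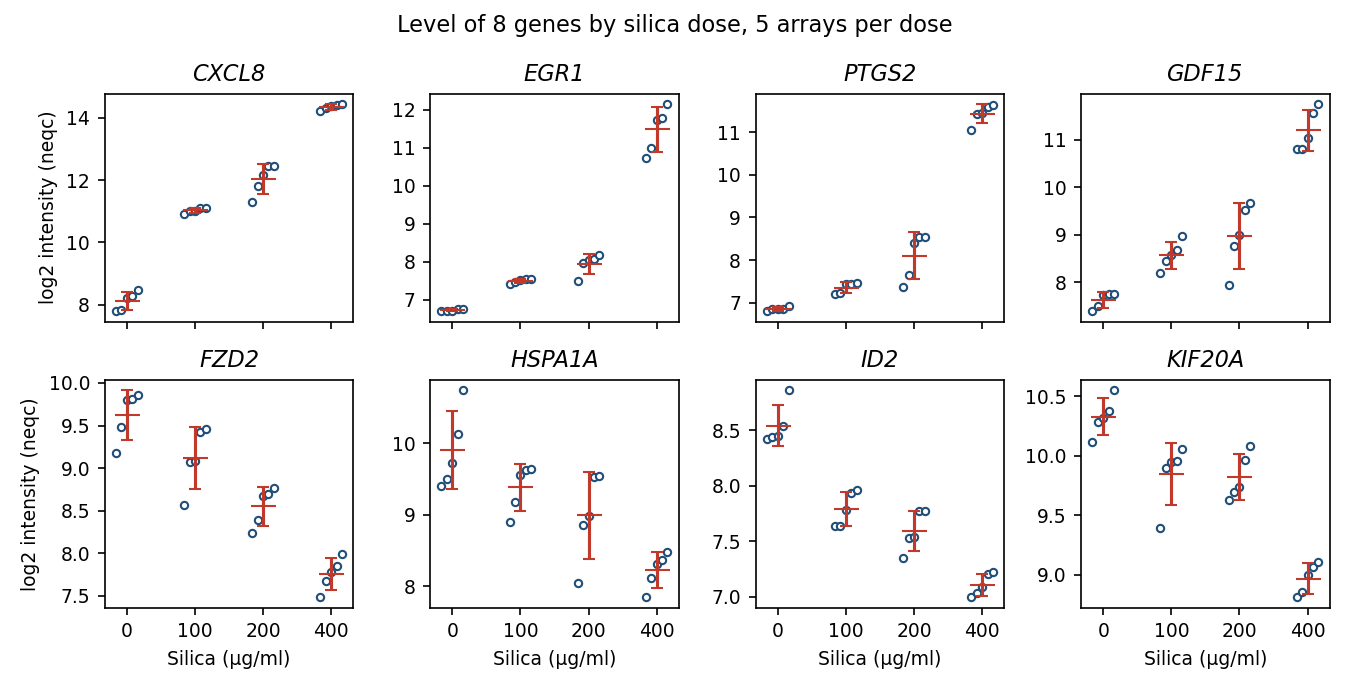
Level of 8 genes (log2 intensity, vertical axis) at each silica dose (µg/ml, horizontal axis, doses drawn as evenly spaced categories), with 5 arrays per dose as circles and mean ± SD in red. CXCL8, EGR1, PTGS2 and GDF15 were higher and FZD2, HSPA1A, ID2 and KIF20A lower on all 5 arrays at 400 µg/ml than on any control array.

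In all, 2183 of 9910 genes (22.0%) changed at 400 µg/ml: 988 rose and 1195 fell. Large changes were mostly rises, with 129 rises and 17 falls of at least 2-fold. With median scaling the count was 1064, of which rises made up 55.5% against 45.3%. The count was 2336 with the order sets as a block, 2261 with the bright arrays as a block and 1586 on the 16 other arrays. Some genes that rose were not detected on every array. Among them KLF6 was detected on 3 of the 5 control arrays and 4 of the 5 at 400 µg/ml, NFKBIZ on 2 and 4, and EREG on 3 and 5. GNL3 was detected on 5 of the 5 control arrays but only 1 of the 5 at 400 µg/ml, although its level there was 0.45 ± 0.09 higher. Camera with an estimated correlation kept 9, 10 and 12 of the 13, 12 and 15 lists shifted at 100, 200 and 400 µg/ml, those not kept being the ones given with a second p above.

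**Figure D3:**
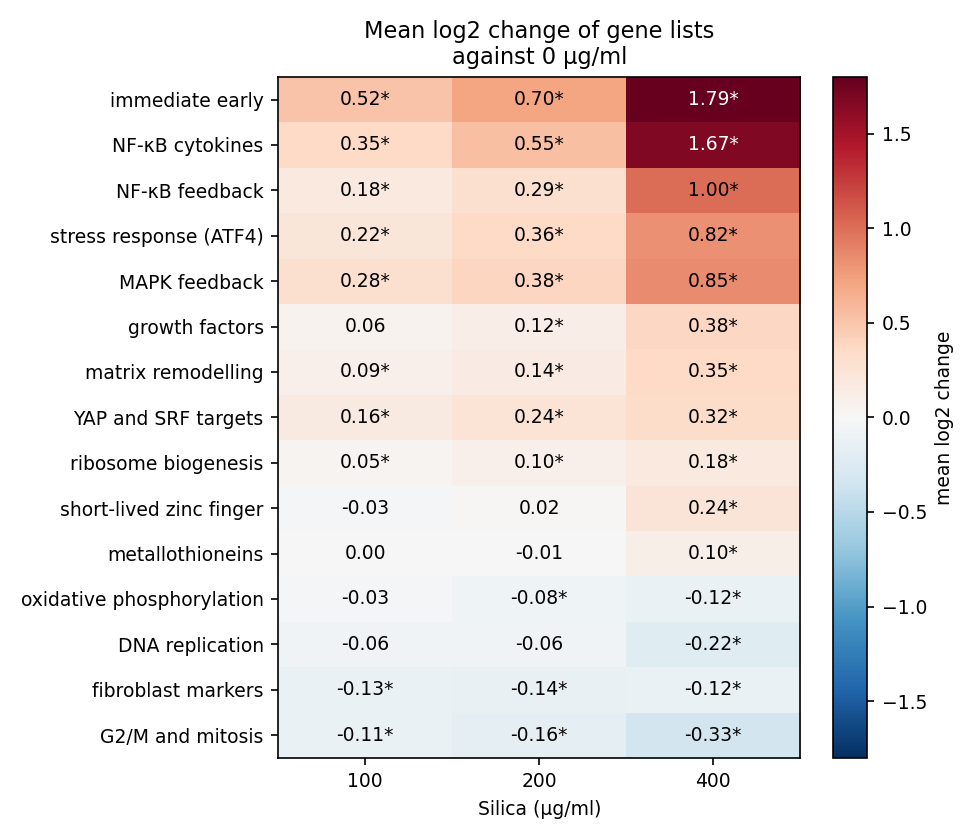
Mean log2 change of the genes of 15 lists (vertical axis) at 100, 200 and 400 µg/ml (horizontal axis) against 0 µg/ml, with an asterisk where camera gave an adjusted p under 0.05. Immediate early genes went from 0.52 to 1.79 and NF-κB cytokines from 0.35 to 1.67, and the mitosis list from -0.11 to -0.33.

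Between 100 and 200 µg/ml STC1 and FST passed the test. STC1 rose by 0.78 ± 0.12 (1.72-fold, adjusted p = 0.0342), from 8.36 ± 0.17 to 9.14 ± 0.27. FST, which encodes the activin antagonist follistatin, rose by 0.70 ± 0.11 (1.63-fold, adjusted p = 0.0342), from 7.55 ± 0.11 to 8.25 ± 0.21. No gene fell by limma (count of 0). Of 9910 genes 522 had an unadjusted p under 0.05 (limma), which is near the rate of 0.05 for unchanged genes. The count was 0 with the order sets as a block (adjusted p = 0.0581 for both genes), with the bright arrays as a block, on the 16 other arrays and without the 3 arrays that deviated together (each by limma). Leaving out 1 array gave 0 genes without 100 µg/ml replicates 1, 3, 4 or 5 or 200 µg/ml replicates 1 to 4, 2 without 100 µg/ml replicate 2 and 11 without 200 µg/ml replicate 5, with adjusted p of STC1 up to 0.166 and of FST up to 0.158 (0.00366 to 1.0 and 0.00120 to 1.0 over all alternatives).

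Between 200 and 400 µg/ml EGR1 rose by 3.53 ± 0.20 (11.5-fold, adjusted p = 2.31e-09), PTGS2 by 3.32 ± 0.19, IL6 by 2.71 ± 0.09 and ZFP36 by 2.68 ± 0.25. FST and STC1 rose by 1.73 ± 0.11 and 1.40 ± 0.12. THEM6 fell by 0.91 ± 0.13, MSRB1 by 0.86 ± 0.12, FAM217B by 0.86 ± 0.13 and KIF20A by 0.85 ± 0.12. In all, 694 genes changed, of which 413 rose and 281 fell. The count was 859 with the order sets as a block, 755 with the bright arrays as a block and 436 on the 16 other arrays, 430 with only the 2 groups in the model and 215 with median scaling. Rises made up 59.5% of the changes, against 69.3% with median scaling and 71.0% without a filter on detection.

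Between 100 and 400 µg/ml PTGS2 rose by 4.08 ± 0.19, EGR1 by 3.97 ± 0.20, CXCL8 by 3.32 ± 0.18 and IL6 by 2.89 ± 0.09. BIRC3 rose by 2.86 ± 0.11, PPP1R15A by 2.30 ± 0.09 and FOSB by 2.23 ± 0.13. FZD2 fell by 1.37 ± 0.17, HSPA1A by 1.15 ± 0.28, KIF20A by 0.88 ± 0.12 and ID2 by 0.68 ± 0.10. In all, 1171 genes changed, of which 621 rose and 550 fell. The count was 1330 with the order sets as a block, 1226 with the bright arrays as a block, 719 on the 16 other arrays and 427 with median scaling, where rises made up 66.7% of the changes against 53%.

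**Figure D4:**
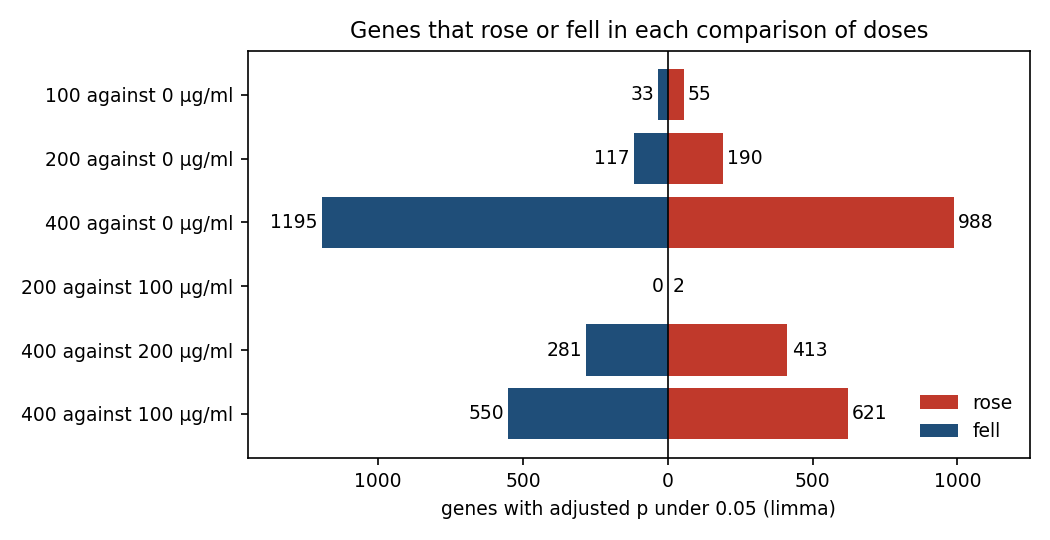
Number of genes that rose (red, to the right) or fell (blue, to the left) at an adjusted p under 0.05 (limma, horizontal axis) in each comparison of doses (vertical axis). The counts against the controls were 55 and 33 at 100 µg/ml, 190 and 117 at 200 µg/ml, and 988 and 1195 at 400 µg/ml.

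A linear trend with dose tested all 4 groups at once. CXCL8 rose by 1.47 ± 0.09 per 100 µg/ml (adjusted p = 1.11e-09), EGR1 by 1.19 ± 0.09, PTGS2 by 1.17 ± 0.08, FOSB by 1.02 ± 0.07 and PPP1R15A by 0.93 ± 0.04. A slope is no constant step, since some genes rose unevenly. Against the controls EGR1 lay 0.77, 1.22 and 4.75 higher at 100, 200 and 400 µg/ml, and CXCL8 2.92, 3.92 and 6.23. FZD2 fell by 0.47 ± 0.04 per 100 µg/ml, HSPA1A by 0.41 ± 0.06, ID2 by 0.33 ± 0.03 and KIF20A by 0.32 ± 0.03. In all, 2274 genes had a trend, 1026 rising and 1248 falling. The count was 2389 with the order sets as a block, 2351 with the bright arrays as a block, 1736 on the 16 other arrays, 1186 without the controls and 1170 with median scaling, where rises made up 55.1% against 45.1%.

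The responses at the 3 doses were compared across genes. Of the genes that changed at 100 µg/ml, 80 also changed in the same direction at 200 µg/ml and 86 at 400 µg/ml, and of those that changed at 200 µg/ml, 290 did so at 400 µg/ml, with 0 in opposite directions in each pair by limma. For 100 and 200, 100 and 400, and 200 and 400 µg/ml, 53, 55 and 179 genes rose at both doses, where independent calls would give 1.05, 5.48 and 18.9. At both doses 27, 31 and 111 genes fell, where independent calls would give 0.390, 3.98 and 14.1. The doses share their control arrays, so their calls are not independent, and no reference with shared controls was computed for these counts. The correlation of log2 changes across 9910 genes was 0.792, 0.717 and 0.807. Simulated unchanged groups against the same controls gave 0.502, 0.50 and 0.50. The covariance was 0.0174, 0.0295 and 0.0419, and simulated as 0.00460 in each pair. With the controls divided between the compared doses the median correlation over 20 divisions was 0.501, 0.536 and 0.661, with lowest and highest values of 0.310 and 0.551, 0.441 and 0.586, and 0.557 and 0.699. The median covariance was then 0.0135, 0.0251 and 0.0374. The simulated values come from shared controls, so the correlations with divided controls are not to be set against them. With divided controls the compared doses share no array, so the noise of a shared control array cannot produce these correlations. A difference in handling of all controls would still enter both responses. No simulation with divided controls was run, so their spread for unchanged groups is not given.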

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

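The tests of the bright arrays and of the 3 arrays for the steep rise, of the HSPA1 copies, of the description number, of the order sets and of the splits by single lists and exchanged arrays were chosen only after the result was seen. A value was singled out where 1 of 5 arrays lay apart from the others of its dose, with a gap to the nearest array that was large against the group's range. Chance does this in about 1 in 20 groups, and 27 of 460 groups (5.87%) did so. Each value below is the gap as a share of the range.

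Median intensity lay apart in control replicate 2 (0.949), 100 µg/ml replicate 3 (0.964), 200 µg/ml replicate 4 (0.959) and 400 µg/ml replicate 4 (0.959), the 4 bright arrays. Control replicate 1 had a lower mean correlation with its group (0.987, gap 0.751). The same array lay high in DUSP5 (0.805) and low in MTF1 (0.737) and SLC2A3 (0.740). ID2 lay high in control replicate 4 (0.731). At 100 µg/ml KIF20A (0.769) and SOD2 (0.724) lay low in replicate 3, XRCC1 (0.765) lay low in replicate 1, and PLIN2 (0.751), CYP2S1 (0.781) and COL1A1 (0.844) lay high in replicate 4. At 200 µg/ml EGR1 (0.720) and CEBPB (0.738) lay low in replicate 5, CTSL (0.761), ID1 (0.921) and KRT7 (0.758) lay low in replicate 1, and CYP2S1 (0.779) lay high in replicate 4. At 400 µg/ml HERPUD1 (0.789) and TNFRSF21 (0.788) lay high in replicate 2, CYP2S1 (0.766) and KRT7 (0.867) lay low in replicate 1, MUC5AC (0.792) lay high in replicate 4 and DDX21 (0.877) lay low there.

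The number of changed genes rose from 307 at 200 µg/ml to 2183 at 400 µg/ml, and neither the 4 bright nor the 3 deviating arrays account for it, since the ratio of the counts was 8.53 and 6.90 without them. A response proportional to dose, with small changes passing the threshold only at the highest dose, would put the share of the 400 µg/ml response reached at 200 µg/ml between 0.4 and 0.6. In arrays not used to choose the genes the share had a median of 0.424 at 200 µg/ml (0.369 to 0.475 in 95% of 100 choices of arrays) and 0.282 at 100 µg/ml (0.253 to 0.301), against 0.5 and 0.25 for exact proportion. At 200 µg/ml the range included 0.5 for falling genes (0.316 to 0.574) and for genes with a control level above 8 (0.397 to 0.522), and not for rising genes (0.375 to 0.454). For the mean over these genes a proportional response and one with another shape cannot be told apart, because the choices straddle the lower bound. This mean does not speak for single genes, some of which rose unevenly, as EGR1 and CXCL8 did in the trend above. A biological change between these doses stays open and untested.

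Of 21 heat shock genes 7 fell at 400 µg/ml, HSPA1A, HSPA1B and DNAJB1 among them. Near-identical HSPA1 copies read by shared probes do not account for all of it, since 4 members outside these copies fell, and neither do the bright arrays, since 71.4% of the falls passed without them. A shift of all genes of that level through the normalization stays open for the list as a whole: its median of -0.06 lay at the 31.1th percentile of 10000 random lists of like level. The list's own adjusted p of 0.129 (camera) missed the threshold, so the falls may belong to single genes and not to the group. An effect of silica on these genes also stays open.

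Control replicate 1, 200 µg/ml replicate 1 and 400 µg/ml replicate 2 deviated together from their groups, along a component with 21.3% of the variance within groups, and all 3 lay in 1 of the 5 order sets, while the bright arrays made up another. A batch shared by the arrays of a set may account for this and is not shown by it, since deviations within sets correlated at 0.123 on average, higher than in any of 10000 random sets with 1 array per dose, and at 0.0421 in the 3 sets without bright or deviating arrays. Wrong dose labels as the shared source are argued against, since 1 of the 3 had a dose score nearest to another group; that array, 200 µg/ml replicate 1 (0.355), and 200 µg/ml replicate 5 (0.341) scored nearest to the mean at 100 µg/ml, yet above all 5 arrays of that dose (0.266 to 0.317). Weaker signal is argued against, since 0 of their values lay outside the range of the other 17 arrays in signal over background or detected sequences, and so is a position shared through the description number, since deviations of arrays with equal numbers correlated at -0.0158 on average. No biological explanation was tested, and what the sets stand for is not given.

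Other splits of the arrays into groups of the same sizes were counted (100 for each result, the real one included), without keeping the order sets together. The real split alone gave as many changed genes for 100 against 0 (1 split, 88 genes, highest other 1), 200 against 0 (1, 307 and 8), 400 against 0 (1, 2183 and 6), 400 against 200 (1, 694 and 22), 400 against 100 (1, 1171 and 14) and the trend (1, 2274 and 4). A random division of these arrays therefore does not account for these counts. The splits treat arrays as independent, so they cannot exclude chance between cultures or a difference in handling. For 200 against 100, 3 splits gave as many (2 genes, highest other 3), which is under 5% of the splits, although another split gave more genes than the real one. For the number of shifted lists the real split alone reached its count at 100 µg/ml (1 split, 13 lists, highest other 9) and 200 µg/ml (1 split, 12 lists, highest other 11). The same limit holds for these, and at 200 µg/ml another split came close. At 400 µg/ml 5 splits gave as many (15 lists, highest other 16), so the number alone does not exclude chance there. The other 4 were all among the 20 splits that exchanged 1 array of each group and so kept part of the difference between the doses (median of 14 lists), while the 79 that exchanged 2 had a median of 3 lists and at most 9. Taken 1 by 1, 11 of the 15 lists had p-values as small in under 5% of the splits, and replication, oxidative phosphorylation, metallothionein and fibroblast markers in 7 to 13 of 100. Heat shock and TGF-β targets at 100 µg/ml and matrix remodelling at 200 µg/ml also did so in 5% or more of the splits (8, 7 and 5 of 100).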

How the results depend on the processing

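The alternatives for the bright arrays, the order sets and the 3 deviating arrays were chosen after the result was seen. A value counted as kept where it stayed on its side of the threshold, even if its sign changed while it passed in neither fit. A change of sign counted as a reversal only where either fit passed the threshold. Over all alternatives except single left-out arrays, values of named genes were kept in 5714 cases, fell short in 249, newly passed in 72 and reversed in 0. For lists the numbers were 1651, 22, 49 and 0. With single arrays left out they were 3394, 164, 13 and 0 for genes and 927, 20, 13 and 0 for lists. Of the 112 named genes called at 400 µg/ml, 93 passed under every alternative run for them (up to 27). These genes were picked from the same arrays by large changes or small p, so their share does not stand for all genes called. Counts that moved by more than 1.5 times are given here, and the cause was not tested except where fewer arrays, fewer genes tested or a fold minimum lower them by construction.

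Median scaling gave 20, 116 and 1064 changed genes at 100, 200 and 400 µg/ml, 0 for 200 against 100, 215 for 400 against 200, 427 for 400 against 100 and 1170 for the trend. Without a filter on detection 58 genes changed at 100 µg/ml. A minimum of 1.5-fold gave 29, 82 and 400 against the controls, 156 for 400 against 200 and 229 for 400 against 100. Without the 4 bright arrays the counts were 45, 186, 436 and 719 for 100 and 200 against 0, 400 against 200 and 400 against 100, with 44, 166, 405 and 678 genes shared with the full set. With only the 2 groups in the model 430 changed for 400 against 200, and without the controls the trend count was 1186. For 200 against 100 limma called 0 genes from the authors' values, with median scaling, cyclic loess, no filter and only the 2 groups. It also called 0 with the replicate number, the brightness set or the order set as a block. Without the bright arrays and without the 3 arrays the count was 0 too, and with array weights it was 5. In the main fit 522 of 9910 genes had an unadjusted p under 0.05 (limma), near the rate for unchanged genes. With the controls divided the correlations of 100 and 200, 100 and 400, and 200 and 400 µg/ml were 0.501, 0.536 and 0.661.

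With the replicate number as a block (the labels do not say that equal numbers are paired) 79, 294 and 2052 genes changed at 100, 200 and 400 µg/ml. Deviations of arrays with equal replicate numbers correlated at 0.0150 on average over 30 pairs, and 6 of 20 arrays correlated best with their own number. Leaving out 1 array gave 61 to 79, 223 to 306 and 1812 to 2028 genes against the controls, 0 to 11 for 200 against 100, 478 to 672 for 400 against 200, 867 to 1110 for 400 against 100 and 1891 to 2341 for the trend, and 10 to 14, 10 to 15 and 14 to 16 lists. The 4 bright arrays, 1 per group, give no count of their own.

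A block by slide was not run, since no slide is named, and lists were not tested with the description number as a random block. Signal over background of 6.4 to 8.88 limits what can be said of weakly expressed genes.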

Other observations

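The tests in this part were fixed in advance, apart from that of the name families below. The family test was not, and the 2 families given were picked out by their p. Several lists were not shifted as a whole at 400 µg/ml (camera) while single members changed. Of 19 genes of the unfolded protein response 4 rose and 2 fell (5 and 2 when adjusted over the list alone; adjusted p = 0.0994), XBP1 by 1.64 ± 0.10 (SE, n = 5 arrays per group, as for all changes here), HERPUD1 by 0.78 ± 0.09 and DNAJB9 by 0.72 ± 0.09. Of 17 p53 targets 4 rose and 2 fell (4 and 2; adjusted p = 0.0994): GADD45A, which is induced by DNA damage, was up by 2.57 ± 0.13 and AEN by 1.66 ± 0.21. Of 22 DNA repair genes 0 rose and 3 fell by limma (2 fell when adjusted over the list alone; adjusted p = 0.170), and XRCC1 was down at -0.17 ± 0.05. Of 23 apoptosis genes 6 rose and 3 fell (8 and 4; adjusted p = 0.119), TNFRSF10A by 1.19 ± 0.11 and the survival gene MCL1 by 1.02 ± 0.13. Of 29 NRF2 targets 4 rose and 4 fell (4 and 5; adjusted p = 0.926), with NFE2L2, which encodes NRF2, at 1.48 ± 0.21 and TXNRD1 at 0.71 ± 0.08. Of 15 other oxidative stress genes 1 rose and 3 fell (2 and 3; adjusted p = 0.652): mitochondrial SOD2 rose by 1.20 ± 0.12 and MSRB2 fell by 0.75 ± 0.15. Of 21 heat shock genes 0 rose and 7 fell (0 and 7; adjusted p = 0.129).

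Lysosome, lipid and metabolic genes also changed singly. Of 32 lysosome genes 5 rose and 1 fell (4 and 1 when adjusted over the list alone; adjusted p = 0.246), NPC1, a lysosomal cholesterol transporter, by 1.81 ± 0.15 and cathepsin L (CTSL) by 0.75 ± 0.07. Of 24 cholesterol genes 3 rose and 2 fell (3 and 2; adjusted p = 0.672), with INSIG1, a regulator of sterol synthesis, at 0.77 ± 0.12. Of 12 fatty acid genes 2 rose and 2 fell (2 and 2; adjusted p = 0.578), with the lipid droplet gene PLIN2 at 0.72 ± 0.09. Of 17 autophagy genes 4 rose and 1 fell (4 and 1; adjusted p = 0.50), with MAP1LC3B at 0.82 ± 0.17. Of 23 hypoxia and glycolysis genes 5 rose and 1 fell (6 and 3; adjusted p = 0.310), with the glucose transporter gene SLC2A3 at 0.67 ± 0.12. Of 14 TGF-β targets 3 rose and 5 fell (3 and 6; adjusted p = 0.639). Of 14 interferon genes 2 rose and 2 fell (2 and 2; adjusted p = 0.983): ISG20 was at 0.84 ± 0.12, and STAT2 at -0.66 ± 0.09. Of 12 xenobiotic response genes 2 rose and 3 fell (2 and 3; adjusted p = 0.672), with TIPARP, a target of the AHR receptor, at 1.42 ± 0.13. Of 11 alveolar lineage genes 0 rose and 1 fell by limma (0 and 1; adjusted p = 0.277), E-cadherin (CDH1) by 0.16 ± 0.02. Of 51 ribosomal protein genes 0 rose and 4 fell (0 and 1; adjusted p = 0.287), RPL27 by 0.24 ± 0.05. Median scaling ended the calls of XRCC1 and RPL27 and the fit without the 3 deviating arrays that of XRCC1. Median, mean and test differed in sign at 400 µg/ml for NRF2 targets (-0.01, 0.07, up), the unfolded protein response (-0.02, 0.16, up), apoptosis (-0.00, 0.16, up), autophagy (-0.01, 0.08, up), TGF-β targets (-0.04, 0.12, down), interferon (-0.01, -0.02, up) and xenobiotic response (-0.05, 0.04, down). They also differed in sign at 100 µg/ml for the cholesterol, fatty acid, autophagy, ribosomal protein and short-lived transcript lists and at 200 µg/ml for metallothioneins and alveolar lineage, with none of these shifted there.

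Fry, which asks whether the genes of a list move 1 way on balance without comparing them with other genes, called 16, 16 and 22 of 32 lists at 100, 200 and 400 µg/ml. Of 108 groups of at least 10 genes with names of the same stem, the collagen (COL) genes lay lower at 100 µg/ml (1 of 13 fell, adjusted p = 0.0441 by camera), where adjusted p = 0.220 with an estimated correlation. The IL genes lay higher at 400 µg/ml (6 of 14 rose, adjusted p = 0.00324), where adjusted p = 0.174 with an estimated correlation. They include IL6, IL1A and IL1B, which were detected on 0 of the 5 control arrays and passed the filter only through treated arrays.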
